A study of Mus musculus with 6 samples.

How the data were processed

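Liver RNA from 3 wild-type and 3 Entpd8 knockout samples was measured by poly(A) RNA sequencing. Per the labels' protocols, RNA was extracted with an RNeasy kit, poly(A) RNA was enriched with a NEBNext module, and libraries were built with a NEBNext Ultra II RNA kit, with no statement in words that strand was kept. Trim Galore, STAR and Salmon and the genome build GRCm38 are named per the submitters' processing notes, and their versions, order, settings and annotation are not given in the sources used here. The deposited table holds expected counts, estimated counts per gene that need not be whole, with 1 column per library and no scaling to a common total, per the file headers and the values. Between 8.38% and 9.32% of genes per library had a value that was not whole. Estimated counts divide reads among similar transcripts by a model, so values of close paralogs are less certain than those of unique genes. Samples were assigned to genotypes by their titles, and each column was tied to the sample whose title holds the column name. No sample was left out.

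The table held 45706 genes, of which 45143 matched a gene symbol. The 563 others carried 0.0379% to 0.0509% of a library and stayed in the fit under their identifiers. Library totals ran from 32768774 to 46473531 counts. Positions, biotypes and transcript lengths came from GENCODE M21, which uses GRCm38. Values were rounded to whole numbers. Genes were filtered with filterByExpr and libraries scaled by TMM, leaving 14069 genes, and the common dispersion was 0.0461. The test was the two-sided quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, R 4.3.3) on genotype alone, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors of log2 fold changes are the size of the log2 fold change divided by the square root of the F statistic. CPM values use library totals scaled by TMM.

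The 23 pathway lists, 14 cell type marker lists and 5 sample check lists were chosen before the data were examined, with the tests, the naming rule and all alternatives except those named as added. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all such lists. The genes named are Entpd8, then the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted gene models, Riken clones and pseudogenes. Of each list described, up to 4 members with the lowest p and a mean log2 CPM of at least 0 could be named, and all members of the sample check lists. Some genes that met these rules were not used here. Of 2461 genes that met the first rule's thresholds, 90 were such models. Genes near Entpd8 were compared with all others by Fisher's exact test. A list symbol that matched no gene was looked up among RefSeq synonyms.

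The fit was tested on simulated counts made from the wild-type means, library sizes and fitted dispersions of 14069 genes. In these, 100 genes were changed by each of 2 fold sizes, and a list of 30 others was shifted 1.5-fold. Among the 13654 genes left after filtering, the fit recovered 71.6% of the genes changed 3-fold and 14.3% of those changed 1.5-fold. It called 8 of 13431 unchanged genes. The simulated genes varied independently, and a smaller share was changed than passed in the real fit (2871 of 14069). These rates therefore need not hold for the real libraries. Each pair of libraries within a group differed by 31.9 to 127 times the variance of counting noise per gene, so none was treated as a duplicate. Alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter, estimation without robust weights, DESeq2 1.42.0, limma voom, a fold minimum of 1.5, a threshold of 0.1, leaving out each library, the replicate number as a block, other set tests and other windows around Entpd8. A fit with the transcript length trend of each library removed (lowess span 0.5, entered as offsets) and a fit without mitochondrially encoded and hemoglobin genes were added after the data were seen. With 3 libraries per group an exact two-sided permutation test cannot go below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.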

Results

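Poly(A)-enriched RNA was sequenced from 6 mouse liver samples, 3 labelled wild type (WT 1 to WT 3) and 3 labelled Entpd8 knockout (KO 1 to KO 3). Entpd8 encodes NTPDase8, an ectonucleotidase that hydrolyses extracellular nucleotides, and the series addresses its part in liver ischemia. The labels do not state whether these livers had undergone ischemia, nor the sex, age or sampling time of the mice. They also do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples. Total counts were 36086780, 39929978 and 32768774 in the wild-type libraries and 40800058, 42833225 and 46473531 in the knockout libraries.

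The first comparison asked whether the targeted transcript was lost in the libraries labelled knockout. Entpd8 fell in all 3 knockout livers (log2 fold change -5.72 ± 0.48 (SE), adjusted p = 0.00151, edgeR). Its expected counts were 1416, 876 and 2034 in WT 1, WT 2 and WT 3, against 15, 29 and 52 in KO 1, KO 2 and KO 3. Scaled to library size (CPM), this was 39.3 ± 17.0 CPM in wild type and 0.733 ± 0.356 CPM in knockout livers (SD, n = 3 per group). The gene, ENSMUSG00000036813, lies on the plus strand of chromosome 2 from 25080304 to 25085716 in GRCm38. Some Entpd8 reads remained in each knockout library, and gene-level counts do not show which exons they covered.

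The main comparison asked which liver transcripts differed between the genotypes. Most immediate-early, heat shock and cholesterol synthesis genes tested rose in knockout livers, as did 19 inflammatory genes and the immunoglobulin genes Igha, Igkc and Jchain. Falls were recorded for 18 acute-phase genes, 8 Kupffer cell markers and 13 cell cycle genes. Among 14069 genes tested, 2871 passed, 1379 higher and 1492 lower in knockout livers. Of these, 649 rose and 494 fell by more than 2-fold. The first principal component of log2 CPM (53.8% of the variance) separated the genotypes, and the second (16.6%) set WT 2 apart from WT 1 and WT 3. The 3 knockout libraries did not overlap the 3 wild-type libraries for 5725 genes (40.7% of those tested, against 10% by chance). The number of genes called was 603 without KO 1, 1594 without KO 2, 1744 without KO 3 and 1653 without WT 1, and without WT 3 the number lower was 973. A test against a fold change of 1.5 passed 323 genes.

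**Figure D1:**
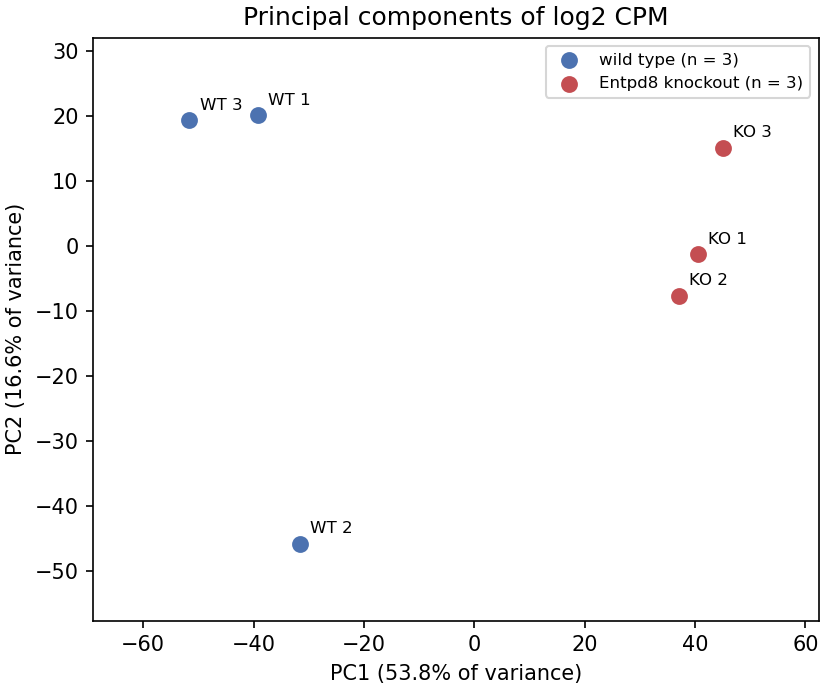
Scores of the 6 libraries on the first and second principal components of log2 CPM, 1 point per library, with the percentage of variance on each axis. The 3 wild-type libraries lie at negative and the 3 knockout libraries at positive values of the first component (53.8% of the variance).

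Immunoglobulin transcripts had the largest rises among genes that met the naming rule, with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, predicted models, Riken clones and pseudogenes left out. Igha, the heavy chain constant region of IgA, rose from 0.271 ± 0.0377 CPM to 22.2 ± 6.07 CPM (SD, n = 3 per group). Its log2 fold change was 6.35 ± 0.28 (SE), adjusted p = 1.41e-04. The kappa light chain Igkc (4.17 ± 0.40, adjusted p = 0.00187) and Jchain, which joins IgA and IgM into polymers (3.99 ± 0.29, adjusted p = 6.96e-04), rose with it. The matricellular protein gene Ccn1 rose by 3.85 ± 0.18 on the log2 scale (adjusted p = 1.41e-04), and the chemokine Cxcl10 by 3.58 ± 0.40 (adjusted p = 0.00338). Further log2 fold changes were 3.40 for Rgs16, a regulator of G protein signalling, 3.29 ± 0.64 for the cytokine Lif and 3.25 for the succinate receptor Sucnr1. The chemokine scavenging receptor Ackr2 rose by 3.19 and Fam13a by 3.18. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose by 3.72 ± 0.90 and the protease inhibitor Serpinb1a by 3.51 ± 0.73. The log2 fold change of Lif was 2.47 without KO 3, and that of Ppp1r3g was 2.59 without KO 2. Ppp1r3g did not pass without any 1 library other than KO 3 (adjusted p up to 0.0914) and Serpinb1a without WT 2, WT 3, KO 1 or KO 3 (adjusted p up to 0.0755). Ppp1r3g and Serpinb1a did not pass with no low-count filter or limma voom (adjusted p up to 0.129).

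A2m, the gene of the protease inhibitor alpha-2-macroglobulin, had the largest fall among genes that met the same rule, from 97.7 ± 71.1 CPM to 1.40 ± 0.483 CPM (SD, n = 3 per group). Its log2 fold change was -6.11 ± 0.85 (SE), adjusted p = 0.00683. Wild-type counts of A2m were 4247, 6131 and 682 in WT 1, WT 2 and WT 3. The macrophage sialoadhesin Siglec1 (-2.84 ± 0.43), the imprinted gene Peg3 (-2.67 ± 0.46), the tight junction gene Marveld3 (-2.51 ± 0.36) and the inhibin subunit gene Inhbe (-2.36 ± 0.30) also fell. Smaller falls were those of Saa3 (-2.24), Nbea (-2.20), the citrate transporter Slc13a5 (-2.14), the topoisomerase Top2a (-2.10), Cyp2b10 (-2.10), AI480526 (-2.05) and Ctcflos (-2.05). Ctcflos overlaps Ctcfl on the other strand, and whether the counts kept the strands apart is not stated in the labels. Without WT 1, the log2 fold change of Top2a was -1.11 and that of Cyp2b10 was -1.14, and without WT 2 that of Saa3 was -1.47. Peg3 did not pass without KO 1 (adjusted p = 0.0586), Saa3 without any 1 library other than WT 3 (adjusted p up to 0.177), Slc13a5 and Cyp2b10 without KO 1, KO 2 or KO 3 (adjusted p up to 0.141) and Top2a without WT 1, KO 1, KO 2 or KO 3 (adjusted p up to 0.160). Saa3 did not pass with RLE size factors, no low-count filter, limma voom, the length trend removed or mitochondrial and hemoglobin genes left out (adjusted p up to 0.194), Slc13a5 with no low-count filter (adjusted p = 0.0772), Top2a with no low-count filter, limma voom or the length trend removed (adjusted p up to 0.0926) and Cyp2b10 with no low-count filter or limma voom (adjusted p up to 0.162).

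**Figure D2:**
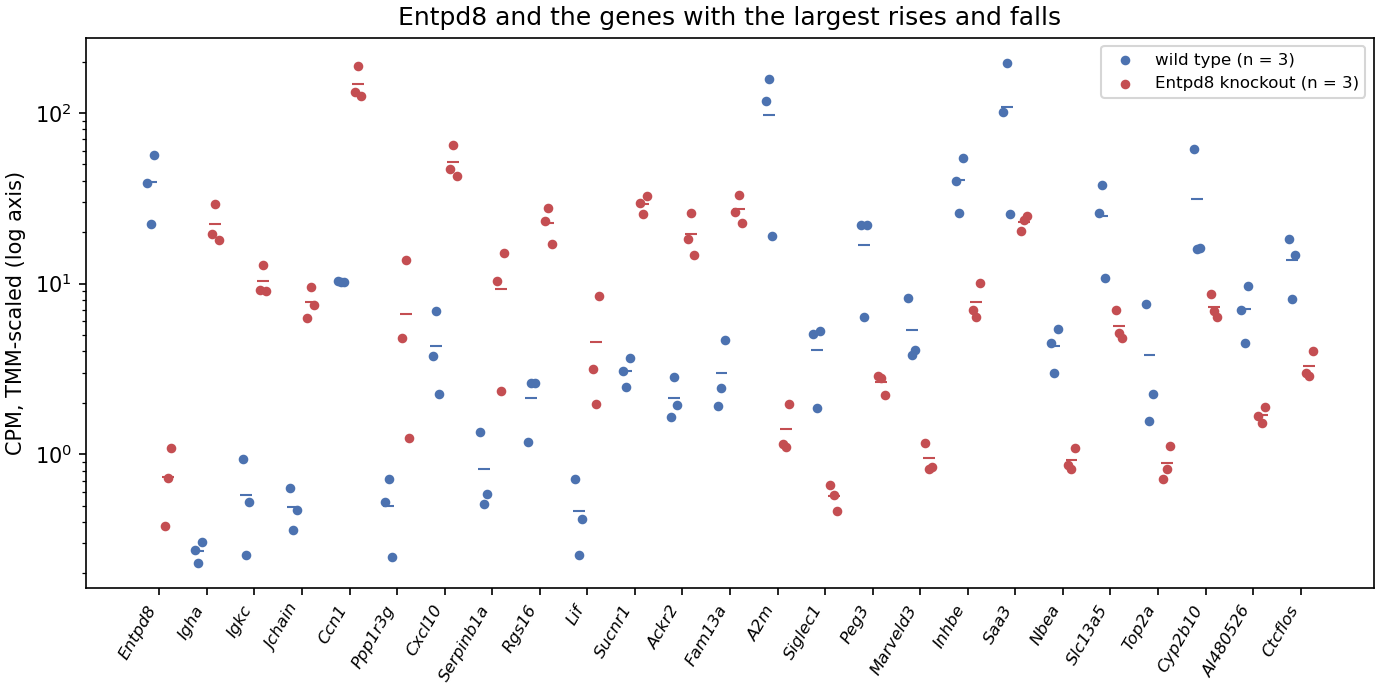
TMM-scaled CPM on a log axis for Entpd8, the 12 genes with the largest rises and the 12 with the largest falls under the naming rule, 1 point per library (n = 3 per group) and a bar at each group mean. For each gene shown, the 3 knockout libraries lie all above or all below the 3 wild-type libraries.

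Gene lists were then compared with the other genes. With the preset correlation, camera called 25 of 37 lists, 21 upward and 4 downward. With an estimated correlation it called 1, cholesterol synthesis. The preset test also called 15 to 27 lists in the 9 other splits of these 6 libraries into 3 and 3. Each of those splits mixed the genotypes on both sides, so part of the genotype difference remained between its sides. The splits therefore cannot tell whether a preset call reflects genotype or other differences between these libraries. Each list is described first by the members that passed. These counts stand against 1379 higher and 1492 lower among all 14069 genes tested. The interferon list, with 4 higher and 4 lower of 41, held about those shares, so called members alone do not mark a list as changed. For 20 of 37 lists the difference in mean log2 CPM was larger between the genotypes than in any other split (exact permutation p = 0.1, the smallest that 3 against 3 allows). The other called lists, those of acute-phase, fatty acid oxidation, amino acid, pericentral, neutrophil and stellate genes, had a difference as large in 1 or more other splits. At a preset correlation of 0.05, calls ended for the lists of fatty acid oxidation, bile acids, amino acids, the cell cycle, pericentral markers and neutrophil markers (adjusted p up to 0.146). Called members beyond the 4 that the naming rule allows per list were named after their values were seen.

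Most immediate-early and heat shock genes tested and 19 of 38 inflammatory genes rose in knockout livers. Of the immediate-early and stress-kinase genes, 24 of 28 tested rose and 0 fell, against 26 and 0 adjusted over the list alone. Besides Ccn1, these included the phosphatase Dusp6 (2.29 ± 0.13) and the transcription factors Myc (2.28 ± 0.13) and Atf3 (3.12 ± 0.30). The immediate-early list had a median log2 fold change of 1.99, with adjusted p = 2.63e-39 in camera and adjusted p = 0.0844 with an estimated correlation. Of the heat shock genes, 15 of 18 tested rose and 0 fell, against 17 and 0 adjusted over the list alone. The HSP40 co-chaperones Dnajb4 (1.72 ± 0.17), Dnaja1 (1.22 ± 0.14) and Dnajb1 (2.70 ± 0.31) were among them. The heat shock list had a median log2 fold change of 1.15, with adjusted p = 1.04e-13 in camera and adjusted p = 0.114 with an estimated correlation. Of the inflammatory cytokine, chemokine and adhesion genes, 19 of 38 tested rose and 0 fell, against 23 and 0 adjusted over the list alone. Nfkbiz (2.08 ± 0.16), a nuclear regulator of NF-kappa-B target genes, and Nfkbia (1.55 ± 0.15), an inhibitor of NF-kappa-B, rose along with Cxcl10 and the chemokine Ccl7 (2.53 ± 0.34). The inflammatory list had a median log2 fold change of 1.17, with adjusted p = 2.35e-14 in camera and adjusted p = 0.175 with an estimated correlation. The share of mitochondrially encoded transcripts was also higher in these knockout libraries (10.9 ± 0.809%) than in wild-type libraries (7.52 ± 0.924%, SD, n = 3 per group).

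The antioxidant regulator Nfe2l2 and the growth arrest genes Gadd45a and Gadd45b also rose. Of the oxidative stress genes, 14 of 31 tested rose and 0 fell, against 16 and 2 adjusted over the list alone. Nfe2l2 (1.36 ± 0.12), sulfiredoxin Srxn1 (1.07 ± 0.13) and heme oxygenase Hmox1 (2.40 ± 0.33) were among them. Oxidative stress defence had a median log2 fold change of 0.51, with adjusted p = 4.01e-07 in camera and adjusted p = 0.0844 with an estimated correlation. Of the cell death and p53 genes, 9 of 36 tested rose and 2 fell (Aifm2 and Bak1), against 9 and 3 adjusted over the list alone. Gadd45a rose by 3.09 ± 0.23 and Gadd45b by 2.43 ± 0.29 on the log2 scale. The cell death list had a median log2 fold change of 0.36, with adjusted p = 0.00189 in camera and adjusted p = 0.145 with an estimated correlation. Of the hypoxia-inducible genes, 8 of 25 tested rose and 1 fell (P4ha2), against 8 and 1 adjusted over the list alone. Bhlhe40 (1.68 ± 0.23), the glucose transporter Slc2a1 (1.04 ± 0.15) and the lipid droplet gene Hilpda (2.91 ± 0.41) rose. The hypoxia list had a median log2 fold change of 0.35, with adjusted p = 0.00119 in camera and adjusted p = 0.521 with an estimated correlation. Of the unfolded protein and integrated stress genes, 3 of 27 tested rose (Ppp1r15a, Fgf21 and Ddit3) and 1 fell (Mthfd2), against 2 and 1 adjusted over the list alone. Ppp1r15a, a phosphatase subunit of that response, rose by 1.98 ± 0.17. The unfolded protein list had a median log2 fold change of 0.01, with adjusted p = 0.323 in camera and adjusted p = 0.845 with an estimated correlation. It passed without WT 2 (adjusted p = 0.00841). Aifm2 and Ddit3 did not pass without any 1 library other than WT 2 (adjusted p up to 0.124), Bak1 and Mthfd2 without any 1 library other than WT 3 (adjusted p up to 0.115), P4ha2 without WT 1 or KO 1 (adjusted p up to 0.0513) and Fgf21 without WT 2, WT 3, KO 1 or KO 3 (adjusted p up to 0.0663). Bak1 did not pass with RLE size factors or no low-count filter (adjusted p up to 0.0566) and Ddit3 with no low-count filter or the length trend removed (adjusted p up to 0.0717).

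Most cholesterol synthesis genes and some fatty acid synthesis genes rose in knockout livers. Of the cholesterol synthesis genes, 18 of 25 tested rose and 0 fell, against 22 and 0 adjusted over the list alone. Squalene synthase Fdft1 rose by 1.51 ± 0.12 on the log2 scale (adjusted p = 7.75e-04), the sterol carrier Stard4 by 1.67 ± 0.15 and Insig1 by 1.91 ± 0.17. Cholesterol synthesis had a median log2 fold change of 0.86, with adjusted p = 1.86e-19 in camera and adjusted p = 0.0403 with an estimated correlation. Of the fatty acid and triglyceride synthesis genes, 12 of 30 tested rose and 0 fell, against 18 and 1 adjusted over the list alone. The transcription factor Srebf1 (2.51 ± 0.16), fatty acid synthase Fasn (1.81 ± 0.20) and Fitm1 (2.39 ± 0.26) were among them. The fatty acid synthesis list had a median log2 fold change of 0.90, with adjusted p = 6.49e-09 in camera and adjusted p = 0.145 with an estimated correlation. Of the fatty acid oxidation and ketogenesis genes, 6 of 35 tested rose and 2 fell (Cpt1a and Cpt2), against 6 and 2 adjusted over the list alone. Pdk4 rose by 2.11 ± 0.35, and Cpt1a, which passes long-chain fatty acids into mitochondria, fell by 0.84 ± 0.16 on the log2 scale. The fatty acid oxidation list had a median log2 fold change of 0.32, with adjusted p = 0.00837 in camera and adjusted p = 0.521 with an estimated correlation. The call was lost without WT 2 (adjusted p = 0.112). Cpt1a and Pdk4 did not pass without KO 1 (adjusted p up to 0.0582) and Cpt2 without WT 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.129).

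Among drug metabolism and glucose genes, the xenobiotic receptor Ahr (1.17 ± 0.12), Cyp2c37 (1.44 ± 0.21) and the glucose transporter Slc2a2 (1.51 ± 0.19) rose. Reads of Cyp2c37 can be shared with related Cyp2c genes. Of the cytochrome P450 and drug metabolism genes, 15 of 45 tested rose and 2 fell (Cyp2b10 and Cyp3a11), against 18 and 4 adjusted over the list alone. Drug metabolism had a median log2 fold change of 0.52, with adjusted p = 2.01e-05 in camera and adjusted p = 0.114 with an estimated correlation. Of the glycolysis and gluconeogenesis genes, 11 of 28 tested rose and 2 fell (Insr and Pck1), against 11 and 3 adjusted over the list alone. The glycolysis list had a median log2 fold change of 0.30, with adjusted p = 0.00119 in camera and adjusted p = 0.444 with an estimated correlation. Of the amino acid and urea genes, 9 of 33 tested rose and 2 fell (Mat1a and Sdsl), against 12 and 2 adjusted over the list alone. Bhmt, a homocysteine methyltransferase, rose by 1.02 ± 0.18. The amino acid list had a median log2 fold change of 0.33, with adjusted p = 0.0305 in camera and adjusted p = 0.599 with an estimated correlation. It lost its call without WT 2 (adjusted p = 0.0661), WT 3 (adjusted p = 0.101), KO 1 (adjusted p = 0.0534) or KO 2 (adjusted p = 0.157). The amino acid list did not pass with library totals alone (adjusted p = 0.0580). Of the bile acid genes, 2 of 28 tested rose (Slc10a1 and Amacr) and 1 fell (Atp8b1), against 1 and 1 adjusted over the list alone. The bile acid importer Slc10a1 rose by 0.84 ± 0.17, and the flippase Atp8b1 fell by 1.07 ± 0.12 on the log2 scale. The bile acid list had a median log2 fold change of 0.45, with adjusted p = 0.0197 in camera and adjusted p = 0.521 with an estimated correlation. The call was lost without WT 2 (adjusted p = 0.145) or KO 2 (adjusted p = 0.0719). Cyp2b10 and Sdsl did not pass without KO 1, KO 2 or KO 3 (adjusted p up to 0.141), Cyp3a11 without WT 1, KO 1, KO 2 or KO 3 (adjusted p up to 0.134), Insr, Bhmt and Slc10a1 without KO 1 (adjusted p up to 0.0652), Pck1 without any 1 library other than WT 2 (adjusted p up to 0.164), Mat1a without KO 1 or KO 2 (adjusted p up to 0.0993) and Amacr without WT 1, WT 2, KO 1 or KO 2 (adjusted p up to 0.130). Cyp2b10 did not pass with no low-count filter or limma voom (adjusted p up to 0.162), Pck1 with RLE size factors (adjusted p = 0.0528), Sdsl with no low-count filter (adjusted p = 0.0535) and Amacr with upper-quartile scaling or library totals alone (adjusted p up to 0.0789).

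Clock-related genes rose in part, with Wee1 at 2.42 ± 0.26, while Clock fell by 0.78 ± 0.12 on the log2 scale. Of the circadian genes, 7 of 22 tested rose and 1 fell (Clock), against 7 and 1 adjusted over the list alone. The circadian list had a median log2 fold change of 0.59, with adjusted p = 0.00119 in camera and adjusted p = 0.159 with an estimated correlation. Of the nuclear-encoded oxidative phosphorylation genes, 4 of 44 tested rose (Sdhb, Uqcrb, Sdhc and Sdha) and 0 fell, against 0 and 0 adjusted over the list alone. Oxidative phosphorylation had a median log2 fold change of 0.29, with adjusted p = 1.52e-04 in camera and adjusted p = 0.705 with an estimated correlation. Mitochondrially encoded transcripts made up 7.52 ± 0.924% of wild-type and 10.9 ± 0.809% of knockout libraries (SD, n = 3 per group), without overlap (two-sided exact permutation p = 0.1, the smallest possible). Sdhb did not pass without WT 1, KO 1 or KO 2 (adjusted p up to 0.0855), Uqcrb without WT 1, WT 3, KO 1 or KO 2 (adjusted p up to 0.121) and Sdhc and Sdha without any 1 library other than WT 2 (adjusted p up to 0.186). Uqcrb did not pass with the length trend removed (adjusted p = 0.113) and Sdhc and Sdha with upper-quartile scaling, library totals alone or no low-count filter (adjusted p up to 0.0887).

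Apcs, Lbp, Fgl1 and Saa2, which encode acute-phase proteins, products of hepatocytes in inflammation, fell in knockout livers. Of the acute-phase genes, 1 of 32 tested rose (Cebpd) and 18 fell, against 1 and 20 adjusted over the list alone. The log2 fold change was -1.77 ± 0.20 for serum amyloid P Apcs, -1.03 ± 0.16 for the lipopolysaccharide-binding protein Lbp, -1.54 ± 0.24 for Fgl1 and -1.87 ± 0.30 for Saa2, a near copy of Saa1. The acute-phase list had a median log2 fold change of -0.85, with adjusted p = 5.84e-07 in camera and adjusted p = 0.444 with an estimated correlation. Its mean log2 CPM was 9.94 in WT 1 and 10.02 in WT 2 but 9.12 in WT 3, against 9.17 in KO 1, 9.15 in KO 2 and a value below that of WT 3 in KO 3, so WT 3 lay within the knockout range. A difference as large was found in 3 of 10 splits, the genotype split included (exact permutation p = 0.3). Of the cell cycle genes, 4 of 40 tested rose (Rrm2, Ccne2, Pcna and Cdc6) and 13 fell, against 5 and 18 adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, rose by 1.86 ± 0.35, and the mitotic gene Cdca8 fell by 1.87 ± 0.48 on the log2 scale. The cell cycle list had a median log2 fold change of -0.87, with adjusted p = 0.0140 in camera and adjusted p = 0.734 with an estimated correlation. The call was lost without WT 1 (adjusted p = 0.120). In WT 1, WT 2 and WT 3 the mean log2 CPM of the list was 1.90, 0.74 and 1.27. In KO 1, KO 2 and KO 3 it was 0.67, 0.62 and 0.69. The cell cycle list did not pass with the stricter filter (adjusted p = 0.600). Cebpd did not pass without WT 1, KO 1, KO 2 or KO 3 (adjusted p up to 0.0919), Rrm2 without KO 1 (adjusted p = 0.0584), Ccne2 without WT 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.0842), Pcna without any 1 library other than WT 2 (adjusted p up to 0.140), Cdc6 without any 1 library other than KO 2 (adjusted p up to 0.151) and Cdca8 without WT 1, KO 1 or KO 2 (adjusted p up to 0.102). Pcna did not pass with library totals alone or the length trend removed (adjusted p up to 0.0956) and Cdc6 with upper-quartile scaling, library totals alone, robust estimation off or limma voom (adjusted p up to 0.0806).

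Fibronectin Fn1 (-1.20 ± 0.14) and the collagen gene Col1a2 (-1.04 ± 0.18) fell, while smooth muscle actin Acta2 rose (1.67 ± 0.32). Of the extracellular matrix genes, 3 of 35 tested rose (Acta2, Lgals1 and Tagln) and 4 fell (Fn1, Col1a2, Sparc and Col1a1), against 4 and 4 adjusted over the list alone. The matrix list had a median log2 fold change of -0.06, with adjusted p = 0.388 in camera and adjusted p = 0.895 with an estimated correlation. It passed without KO 3 (adjusted p = 0.0227). Of the coagulation and complement genes, 2 of 40 tested rose (Mbl2 and C8g) and 4 fell (C3, C4bp, C1qa and C1qb), against 2 and 3 adjusted over the list alone. Complement C3 fell by 1.06 ± 0.23 and the lectin Mbl2 rose by 0.79 ± 0.13 on the log2 scale. The coagulation list had a median log2 fold change of -0.03, with adjusted p = 0.428 in camera and adjusted p = 0.895 with an estimated correlation. Of the interferon response genes, 4 of 41 tested rose (Oasl1, Gbp4, Irf1 and Ifit2) and 4 fell (Zbp1, Oas1g, Stat2 and Oas3), against 4 and 4 adjusted over the list alone. Oasl1 rose by 1.44 ± 0.20 and Zbp1 fell by 1.37 ± 0.20 on the log2 scale. The interferon list had a median log2 fold change of -0.16, with adjusted p = 0.560 in camera and adjusted p = 0.895 with an estimated correlation. It passed without WT 1 (adjusted p = 0.0437). Col1a2, Acta2 and Mbl2 did not pass without KO 1 (adjusted p up to 0.0576), Lgals1 without WT 2, WT 3 or KO 1 (adjusted p up to 0.0755), Tagln without WT 1, WT 3, KO 1 or KO 3 (adjusted p up to 0.108), Sparc without WT 1, KO 1 or KO 2 (adjusted p up to 0.0915), Col1a1, C4bp, C1qa, C1qb and Ifit2 without any 1 library other than WT 2 (adjusted p up to 0.139) and C8g without WT 1, WT 3, KO 1 or KO 2 (adjusted p up to 0.102). C3 did not pass without KO 1 or KO 2 (adjusted p up to 0.0819), Gbp4 without WT 1 or KO 1 (adjusted p up to 0.0580), Irf1 and Oas1g without WT 1, KO 1 or KO 3 (adjusted p up to 0.107), Stat2 without any 1 library other than WT 1 (adjusted p up to 0.153) and Oas3 without WT 1, WT 2, KO 1 or KO 3 (adjusted p up to 0.152). Lgals1 did not pass with no low-count filter or the length trend removed (adjusted p up to 0.0626), Tagln with library totals alone or the length trend removed (adjusted p up to 0.0611), C1qb with no low-count filter (adjusted p = 0.0578), Irf1 with library totals alone (adjusted p = 0.0555), Ifit2 with upper-quartile scaling (adjusted p = 0.0529) and Stat2 and Oas3 with the length trend removed (adjusted p up to 0.0800).

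Because the deleted enzyme acts on extracellular nucleotides, lists of related enzymes, receptors and transporters were examined. Membership of a list does not show where in the cell an enzyme acts. Of the ectonucleotide hydrolysis genes other than Entpd8, 3 of 17 tested rose (Alpl, Enpp2 and Entpd3) and 4 fell (Cant1, Enpp4, Entpd7 and Acpp), against 3 and 4 adjusted over the list alone. Cant1, a nucleotidase, fell by 0.70 ± 0.10 on the log2 scale, Enpp4 fell by 0.83 ± 0.14, Entpd7 fell by 1.30 ± 0.24 and the phosphatase Acpp fell by 1.08 ± 0.20. Ectonucleotide hydrolysis had a median log2 fold change of 0.18, with adjusted p = 0.829 in camera and adjusted p = 0.895 with an estimated correlation. Of the purinergic receptors and transporters, 1 of 19 tested rose (Slc28a1) and 1 fell (Adora1), against 1 and 0 adjusted over the list alone. Slc28a1, a nucleoside transporter, had 1, 0 and 0 counts in WT 1, WT 2 and WT 3 and 15, 11 and 23 in KO 1, KO 2 and KO 3. The adenosine receptor Adora1 fell by 1.09 ± 0.30 on the log2 scale (adjusted p = 0.0398). The nucleotide receptor P2ry2 had a log2 fold change of 0.84 ± 0.28 and did not pass (adjusted p = 0.0760). The purinergic list had a median log2 fold change of 0.03, with adjusted p = 0.674 in camera and adjusted p = 0.895 with an estimated correlation. Enpp2 did not pass without WT 1, KO 1 or KO 2 (adjusted p up to 0.102), Entpd3 without any 1 library (adjusted p up to 0.137), Enpp4 without KO 1 (adjusted p = 0.0513) and Adora1 without any 1 library other than WT 2 (adjusted p up to 0.121). Entpd3 did not pass with upper-quartile scaling (adjusted p = 0.0519) and Adora1 with no low-count filter or the length trend removed (adjusted p up to 0.0811).

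Resident macrophage genes such as Cd163 and Clec4f fell, and immunoglobulin genes, transcribed in antibody-producing cells, rose. Of the Kupffer cell markers, 0 of 16 tested rose and 8 fell, against 0 and 12 adjusted over the list alone. The scavenger receptor Cd163 (-1.69 ± 0.26) and the lectin Clec4f (-1.62 ± 0.26) were among them. The Kupffer list had a median log2 fold change of -1.06, with adjusted p = 1.25e-06 in camera and adjusted p = 0.444 with an estimated correlation. Of the B and plasma cell markers, 5 of 11 tested rose (Igha, Jchain, Igkc, Ighg2b and Ighg2c) and 0 fell, against 6 and 0 adjusted over the list alone. Ighg2b rose by 4.30 ± 0.46 beside Igha, Igkc and Jchain, and its reads can be shared with other Ighg genes. The B cell list had a median log2 fold change of 2.35, with adjusted p = 1.26e-11 in camera and adjusted p = 0.0844 with an estimated correlation. Of the erythroid and platelet markers, 6 of 13 tested rose and 0 fell, against 9 and 0 adjusted over the list alone. The hemoglobin genes Hba-a2 (1.74 ± 0.21) and Hbb-bs (1.95 ± 0.24) rose, and each shares reads with a near copy. The erythroid list had a median log2 fold change of 0.65, with adjusted p = 5.25e-06 in camera and adjusted p = 0.200 with an estimated correlation. The erythroid list did not pass with mitochondrial and hemoglobin genes left out, which takes away its hemoglobin members (adjusted p = 0.0571). Hemoglobin transcripts made up 0.0370 ± 0.0101% of wild-type and 0.124 ± 0.0229% of knockout libraries (SD, n = 3 per group).

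H2-Ab1, H2-Aa, H2-Eb1 and Cd74, which serve antigen presentation, rose, as did the low-expressed T and NK cell genes Trbc2, Il7r, Gzmb and Cd3g. Of the T and NK cell markers, 4 of 16 tested rose (Trbc2, Il7r, Gzmb and Cd3g) and 0 fell, against 12 and 0 adjusted over the list alone. The T cell chemokine Ccl5 (mean log2 CPM 0.50) had a log2 fold change of 1.08 ± 0.35 and did not pass (adjusted p = 0.0608). The T and NK list had a median log2 fold change of 1.22, with adjusted p = 8.59e-05 in camera and adjusted p = 0.0844 with an estimated correlation. Mean log2 CPM of its members was -1.56, -1.55 and -1.86 in WT 1, WT 2 and WT 3. In KO 1, KO 2 and KO 3 that mean was -0.60, -0.42 and -0.49, still low. Of the dendritic cell and antigen presentation markers, 4 of 14 tested rose (H2-Ab1, H2-Aa, H2-Eb1 and Cd74) and 1 fell (Clec9a), against 5 and 1 adjusted over the list alone. Clec9a, a receptor of dendritic cells, fell by 1.76 ± 0.34 on the log2 scale. The dendritic list had a median log2 fold change of 0.46, with adjusted p = 0.0794 in camera and adjusted p = 0.521 with an estimated correlation. A call was made without WT 1 (adjusted p = 0.0447). The dendritic list passed with no low-count filter (adjusted p = 0.0463). Of the neutrophil markers, 0 of 20 tested rose and 1 fell (Fpr1), against 0 and 0 adjusted over the list alone. The neutrophil list had a median log2 fold change of 0.80, with adjusted p = 0.0263 in camera and adjusted p = 0.734 with an estimated correlation. It lost its call without WT 2 (adjusted p = 0.174), WT 3 (adjusted p = 0.150), KO 2 (adjusted p = 0.0732) or KO 3 (adjusted p = 0.0567). The neutrophil list did not pass with the stricter filter (adjusted p = 0.0590) or the length trend removed (adjusted p = 0.0789). The list's median and test pointed up, whereas Fpr1, its called member, fell. In WT 1 the mean log2 CPM of the neutrophil list was 2.21, above the 1.69, 1.99 and 1.99 of KO 1, KO 2 and KO 3. In WT 2 and WT 3 it was 0.78 and -0.21. Of the monocyte and recruited macrophage markers, 0 of 20 tested rose and 1 fell (Fn1), against 0 and 1 adjusted over the list alone. The monocyte list had a median log2 fold change of 0.32, with adjusted p = 0.904 in camera and adjusted p = 0.964 with an estimated correlation. H2-Ab1 did not pass without WT 3 or KO 1 (adjusted p up to 0.110), H2-Aa without any 1 library (adjusted p up to 0.142), H2-Eb1 and Cd74 without any 1 library other than KO 2 (adjusted p up to 0.162), Trbc2 and Clec9a without KO 1 (adjusted p up to 0.0665), Il7r without WT 1, KO 1 or KO 2 (adjusted p up to 0.0666) and Gzmb without WT 3, KO 1 or KO 2 (adjusted p up to 0.0996). Cd3g and Fpr1 did not pass without any 1 library other than WT 2 (adjusted p up to 0.134). H2-Ab1 did not pass with the length trend removed (adjusted p = 0.0532), H2-Aa with library totals alone (adjusted p = 0.0869), H2-Eb1 with library totals alone or the length trend removed (adjusted p up to 0.0807), Cd74 with upper-quartile scaling, library totals alone or the length trend removed (adjusted p up to 0.108), Cd3g with no low-count filter or DESeq2 (adjusted p up to 0.0697) and Fpr1 with RLE size factors or limma voom (adjusted p up to 0.0558).

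Among structural cells of the liver, the stellate cell gene Hand2 fell by 1.21 ± 0.17 on the log2 scale and the biliary genes Krt19 (2.34 ± 0.42) and Epcam (1.83 ± 0.34) rose. Of the stellate cell markers, 0 of 20 tested rose and 2 fell (Hand2 and Vipr1), against 0 and 2 adjusted over the list alone. The stellate list had a median log2 fold change of -0.45, with adjusted p = 0.00465 in camera and adjusted p = 0.586 with an estimated correlation. It lost its call without KO 2 (adjusted p = 0.0605). Of the cholangiocyte markers, 3 of 15 tested rose (Krt19, Epcam and Cldn4) and 0 fell, against 6 and 0 adjusted over the list alone. The cholangiocyte list had a median log2 fold change of 0.63, with adjusted p = 0.00693 in camera and adjusted p = 0.471 with an estimated correlation. The cholangiocyte list did not pass with the stricter filter (adjusted p = 0.0684). Of the sinusoidal endothelial markers, 1 of 23 tested rose (Ehd3) and 2 fell (Gpr182 and Stab1), against 1 and 1 adjusted over the list alone. The endothelial list had a median log2 fold change of -0.04, with adjusted p = 0.560 in camera and adjusted p = 0.895 with an estimated correlation. It passed without KO 3 (adjusted p = 0.0408). Of the general hepatocyte markers, 3 of 21 tested rose (Asgr2, Rbp4 and Apoa2) and 1 fell (Fgb), against 3 and 1 adjusted over the list alone. The hepatocyte list had a median log2 fold change of 0.13, with adjusted p = 0.361 in camera and adjusted p = 0.895 with an estimated correlation. Of the pericentral hepatocyte markers, 8 of 20 tested rose and 1 fell (Tbx3), against 8 and 1 adjusted over the list alone. Rgn, a pericentral calcium-binding protein gene, rose by 1.06 ± 0.14. The pericentral list had a median log2 fold change of 0.38, with adjusted p = 0.0107 in camera and adjusted p = 0.471 with an estimated correlation. It lost its call without WT 2 (adjusted p = 0.0987). Of the periportal hepatocyte markers, 3 of 21 tested rose (Etnppl, Pigr and Spp2) and 2 fell (Sdsl and Pck1), against 4 and 2 adjusted over the list alone. The periportal list had a median log2 fold change of 0.15, with adjusted p = 0.297 in camera and adjusted p = 0.834 with an estimated correlation. Of the pancreas, muscle, fat and mesothelial markers, 1 of 5 tested rose (Cela1) and 0 fell, against 1 and 0 adjusted over the list alone. This list of other tissues had a median log2 fold change of 0.25, with adjusted p = 0.560 in camera and adjusted p = 0.734 with an estimated correlation. Vipr1, Cldn4 and Gpr182 did not pass without KO 1 (adjusted p up to 0.0603), Ehd3 without WT 1 or KO 1 (adjusted p up to 0.0667), Stab1 and Spp2 without any 1 library other than KO 3 (adjusted p up to 0.162), Rbp4 without KO 1 or KO 2 (adjusted p up to 0.0843), Apoa2 without WT 1, WT 3, KO 1 or KO 2 (adjusted p up to 0.119) and Fgb without any 1 library other than WT 3 (adjusted p up to 0.132). Tbx3 did not pass without WT 1, KO 1, KO 2 or KO 3 (adjusted p up to 0.0914), Pigr without any 1 library other than WT 1 (adjusted p up to 0.187), Sdsl without KO 1, KO 2 or KO 3 (adjusted p up to 0.0764) and Pck1 without any 1 library other than WT 2 (adjusted p up to 0.164). Stab1, Apoa2 and Fgb did not pass with the length trend removed (adjusted p up to 0.0737), Pigr with upper-quartile scaling or library totals alone (adjusted p up to 0.0716), Spp2 with upper-quartile scaling, library totals alone or the length trend removed (adjusted p up to 0.0817), Sdsl with no low-count filter (adjusted p = 0.0535) and Pck1 with RLE size factors (adjusted p = 0.0528).

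**Figure D3:**
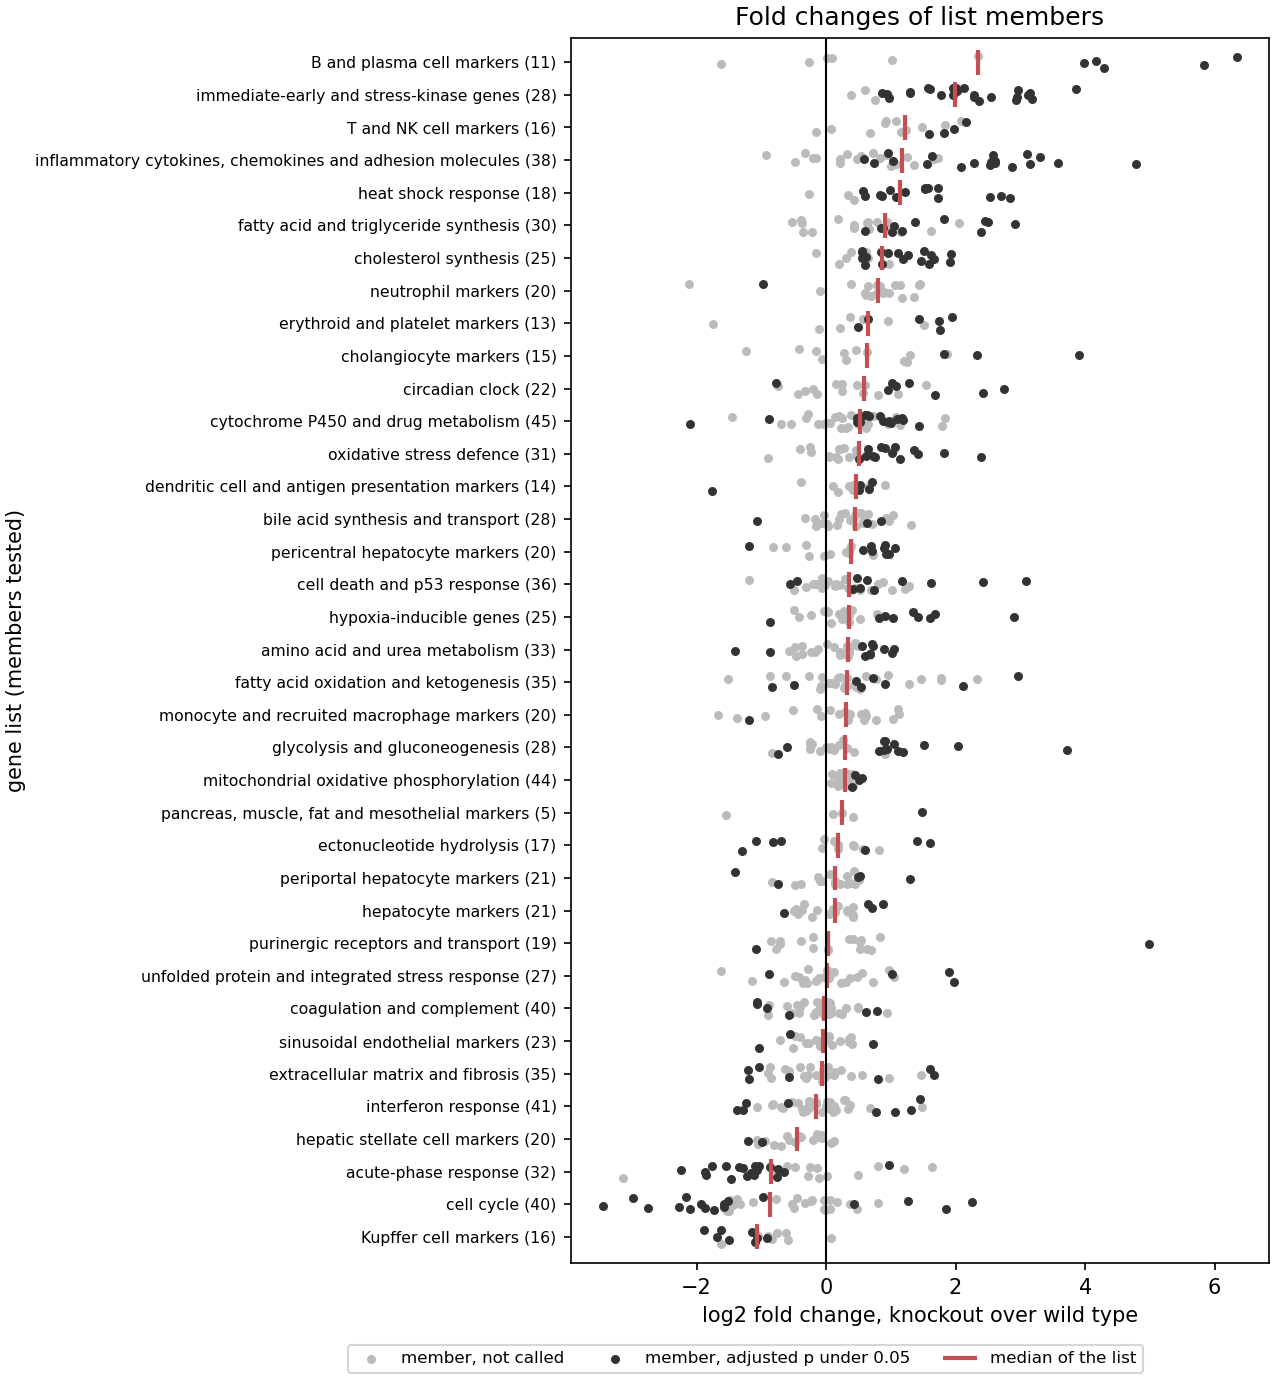
Log2 fold change (knockout over wild type) of every tested member of each pathway and cell type list, ordered by the list median, with the number of members tested after each name. Dark points passed an adjusted p under 0.05, grey points did not, and the red bar is the list median, 1.99 for immediate-early and stress-kinase genes and -1.06 for Kupffer cell markers.

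Sex and strain were checked with lists fixed in the same way. Y-linked genes were detected in all 6 libraries, with log2 fold changes of -0.69 ± 0.14 for Uty, -0.67 ± 0.15 for Kdm5d, 0.25 ± 0.11 for Eif2s3y and 0.06 ± 0.12 for Ddx3y. Uty and Kdm5d fell, and 2 fell adjusted over the list alone. Xist, the X inactivation transcript of female cells, had 1 to 6 counts per library and was not tested. Y-linked expression with so few Xist counts in every library argues against a difference in sex between the groups. Of the male-biased liver genes, 4 of 22 tested rose (Elovl3, Susd4, Hsd3b5 and Gstp2) and 0 fell, against 4 and 1 adjusted over the list alone. Of the female-biased liver genes, 1 of 16 tested rose (Cyp2a4) and 0 fell, against 1 and 0 adjusted over the list alone. Their medians were 0.24 and 0.90 on the log2 scale. Nnt, part of which is deleted in C57BL/6J mice, rose by 0.40 ± 0.11 (adjusted p = 0.0355). Uty and Gstp2 did not pass without KO 1 (adjusted p up to 0.0580), Kdm5d without WT 1, WT 3, KO 1 or KO 2 (adjusted p up to 0.0777), Hsd3b5 without KO 1 or KO 2 (adjusted p up to 0.0664), Cyp2a4 without WT 1 or KO 1 (adjusted p up to 0.0566) and Nnt without any 1 library other than WT 3 (adjusted p up to 0.128). Hsd3b5 did not pass with no low-count filter (adjusted p = 0.0822), Cyp2a4 with limma voom (adjusted p = 0.0507) and Nnt with upper-quartile scaling, library totals alone or no low-count filter (adjusted p up to 0.135).

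The last comparison asked whether changed genes gathered around the deleted locus, where a knockout allele can carry linked variants. Leaving out Entpd8 itself, 42 of 208 tested genes within 10 Mb were called (14 higher and 28 lower), 20.2%. Elsewhere, among genes with an annotated position, 2819 of 13814 were called, 20.4%. The odds ratio was 0.987 (95% confidence interval 0.684 to 1.40, two-sided Fisher's exact test, p = 1). It was 1.04 without WT 1, 1.14 without KO 1 and 1.08 within 5 Mb. Narrower windows were not tested, so a gathering of changed genes closer to Entpd8 stays open. Tor4a, the nearest called gene at 107 kb, fell by 1.51 ± 0.26 on the log2 scale. Fam166a, 133 kb away, had 0, 2 and 0 counts in WT 1, WT 2 and WT 3 and 28, 43 and 34 in KO 1, KO 2 and KO 3 (adjusted p = 0.00508). Tor4a and Fam166a were chosen after their values were seen. Tor4a did not pass without KO 1 (adjusted p = 0.0521).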

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

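The alternatives that removed the length trend or left out mitochondrial and hemoglobin genes were chosen after the data were seen. Entpd8 kept its direction and passed under each alternative run for it. With 1 library left out, 603 to 3080 genes were called (385 to 1390 higher and 218 to 1690 lower) and 21 to 26 lists, from fits with fewer samples. Of the 603 genes called without KO 1, 597 were among the 2871 reported. The replicate numbers gave no sign of pairing. Deviations of same-numbered libraries from their group means correlated across genes at -0.076, 0.013 and -0.085. Differently numbered libraries of the 2 genotypes gave -0.118 to 0.164. With 3 libraries per group, such correlations cannot exclude a pairing. With the number as a replicate block, 1468 genes were called (807 higher and 661 lower), with fewer residual degrees of freedom. By construction, a fold minimum of 1.5 passed fewer genes (323, with 230 higher and 93 lower) and a threshold of 0.1 more (2249 lower). The other scalings, filters and tools gave 2606 to 3573 genes. More genes were lower than higher with library totals alone (1036 higher and 1570 lower, with a median log2 fold change of all genes of -0.10) and upper-quartile scaling (1187 and 1742), and more were higher with RLE size factors (1454 and 1345), DESeq2 (1869 and 1704) and the length trend removed (1465 and 1285). No gene called both there and in the reported fit changed sign. An estimated correlation left 1 list called and the directional test of fry 13. The odds ratio near Entpd8 was 1.08 within 5 Mb and 0.75 to 1.14 with 1 library left out. Thinning each library to the smallest total kept a share of 0.925 to 0.941 of the calls over 5 draws.

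Some named genes and lists changed direction, none of which passed in the reported fit or in the fit that changed it, and the cause was not tested. With upper-quartile scaling, log2 fold changes became -0.025 for C6. With library totals alone, log2 fold changes became -0.0059 for Ddx3y, -0.085 for C6, -0.023 for Cyp2c40 and -0.028 for Fmo2. With limma voom, log2 fold changes became 0.043 for Mup20 and -0.020 for Selenbp2. With the replicate block, log2 fold changes became 0.048 for Mup20. With the length trend removed, log2 fold changes became -0.017 for Mup7, -0.011 for Cyp2c40 and -0.029 for Rarres1. Adjusted p for lists became 0.851 for monocyte and recruited macrophage markers with no low-count filter, 0.951 for ectonucleotide hydrolysis with the stricter filter and 0.883 for monocyte and recruited macrophage markers with the length trend removed. With 1 library left out, log2 fold changes ranged from -0.095 to 0.33 for Mup7, -0.22 to 0.30 for C6, -0.51 to 0.69 for Selenbp2, -0.32 to 0.66 for Cyp2c69, -0.41 to 0.53 for Cyp2c40, -0.24 to 0.45 for Fmo2, -0.34 to 0.24 for Cyp7b1, -0.48 to 0.29 for Mup20, -1.17 to 0.37 for Serpina4-ps1, -0.015 to 0.15 for Ddx3y, -0.44 to 0.17 for Mup11, -0.094 to 0.31 for Rarres1, -0.69 to 0.11 for Gstp1, -0.030 to 1.56 for A1bg and -0.0083 to 1.61 for Ntrk2. Adjusted p of lists then ranged from 0.00841 to 0.498 for unfolded protein and integrated stress response, 0.268 to 0.738 for purinergic receptors and transport, 0.0437 to 0.900 for interferon response, 0.0837 to 0.967 for monocyte and recruited macrophage markers, 0.0227 to 0.621 for extracellular matrix and fibrosis, 0.0408 to 0.674 for sinusoidal endothelial markers and 0.143 to 0.952 for coagulation and complement.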

Other observations

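The tests of handling, of the hepatocyte share, of the immunoglobulin to hemoglobin ratio and of dilution and gain by blood, the removal of the length trend, the splits for lists and the comparison of zinc finger genes were chosen after the main results were seen. Zinc finger genes with a Zfp symbol, a group noticed in these data, were often among the genes that fell. Of 343 tested, 96 were lower and 10 higher, against 1396 lower among 13726 other genes (odds ratio 3.43). The median log2 fold change was -0.42, with p = 0.00845 in camera with an estimated correlation, and 1 of 10 splits, the genotype split itself, had a difference as large. Having been noticed and tested in the same libraries, this remains a hypothesis. With the length trend removed, 87 Zfp genes were lower (odds ratio 3.55).

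The genotype split called 2871 genes and the highest of the other splits of the 6 libraries called 0 in edgeR (125 to 770 genes at an unadjusted p under 0.05, against 5063). As many genes were called in 1 of 10 splits, the genotype split included. For lists with the preset correlation, the genotype split called 25, the highest other split called 27, and 2 of 10 gave as many, the genotype split included. Both sets of 10 splits are too few for a share under 0.05. The other splits mixed the genotypes on each side, which leaves part of the genotype difference between sides and widens the spread within them. Their counts are therefore not those of a comparison free of genotype. The largest log2 fold change of a Y-linked gene was 0.69 in size, and 1.46% of called genes lay within 10 Mb of Entpd8.

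Genes were called in both directions between the genotypes, and a difference in depth as the cause is argued against by thinning, which kept a share of at least 0.925 of the calls. Dilution by blood as the whole cause of the falls is argued against by hemoglobin, at most 0.145% of a library, where the smallest fall called would need 21.0% of added RNA. Erythroid and platelet markers had a median of 0.65, between the bounds set beforehand for and against blood. As the whole cause of the rises blood is argued against, because the other 1369 genes called higher, mitochondrially encoded genes left out, together gained at least 56.1 times the CPM that hemoglobin gained, while single transcripts stay open. Loss of Entpd8 stays open as a biological explanation, beside differences in age, litter or sampling that the labels do not give.

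Immediate-early and heat shock genes rose in knockout livers, with 39 of 46 members called higher. Short transcripts had higher fold changes in general (Spearman correlation of log2 fold change with transcript length -0.18 across 14023 genes, which are not independent replicates). Removing that trend left a median log2 fold change of 1.60 with 38 members called, which argues against it as the whole cause. Handling or delay before the tissue was frozen may raise the same genes, and at a median of 1.59 before removal it cannot be told apart from genotype, because the labels give no handling times and the mitochondrially encoded share moved with it (7.52 ± 0.924% in wild-type and 10.9 ± 0.809% in knockout libraries, SD, n = 3 per group, without overlap). An effect of Entpd8 loss, or of ischemia if these livers underwent it, stays open and untested.

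Immunoglobulin transcripts rose while 8 of 16 tested Kupffer cell markers fell. The Kupffer list was not called in camera with an estimated correlation (adjusted p = 0.444). A lower share of hepatocytes would raise the markers of other cell types alike, which is argued against by 7 marker lists outside this pattern. Their lowest median log2 fold change was -0.45, for stellate cells. Their highest upper quartile was 1.83, for T and NK cells. That quartile lay little below a bound of 1.99, set after the data were seen from the rise of 3.99 for Jchain. Blood of one composition would keep immunoglobulin and hemoglobin transcripts in one ratio, but the mean log2 ratio was -6.22 ± 0.32 in wild-type and -4.36 ± 0.32 in knockout libraries (SD, n = 3 per group), a difference of 1.85 without overlap. Differences in age, litter or microbial exposure were not tested, and the labels name 1 facility for both genotypes. A change in plasma cells and resident macrophages with loss of Entpd8 may be a further explanation, which these libraries cannot separate from such differences.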
